A study of Lonchura striata with 2 samples.

How the data were processed

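Cells of HVC and of the robust nucleus of the arcopallium (RA), song premotor regions of the songbird brain, were profiled with the 10x Genomics 3′ v2 droplet chemistry. According to the labels' protocols, tissue came from 3 adult male Bengalese finches aged 199 to 203 days after hatching. Both nuclei were dissected from 260 µm slices, dissociated in pronase for 45 minutes at 37 °C, and sorted to leave out cells that took up DAPI. The labels give 1 library per region. No column assigns a cell to a bird, so the birds of a library could not be separated, and the fits planned for the case that cells could be assigned to birds do not apply. The HVC and RA samples were mapped to their columns by the region in their titles. No column of any other sample was found.

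The deposited table holds raw UMI counts per gene and cell, made with Cell Ranger 3.0.1 per the submitters' processing notes. The genome build, the annotation and the filter on cells are not given in the sources used here. The lowest UMI count of a deposited cell was 418 and the highest mitochondrial share 39.7%. A deposited table of the cells gives the region, the cluster named by the authors, the UMI count, the gene count and the mitochondrial fraction of UMIs, which its header calls a percent. In all 4110 cells the UMI and gene counts equalled those recomputed from the count table, and the mitochondrial fraction lay within 0.01 of it. Of the 4110 cells, 2 carried another region name, arco, and entered no comparison. Another 8 barcodes occurred in both channels. Of 19857 gene symbols, 12386 (62.4%) were found in the RefSeq name table of assembly bLonStr1.mat, which was used for names only, and 5404 were locus numbers. No genome was used and no coordinates are given.

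The authors' 27 clusters were taken as deposited and joined into 11 classes by their names. How the authors made the clusters is not given in the sources used here. As a check, the 10 genes with the largest fold of each cluster were set against the marker lists fixed before the data were examined. Only the 3-cell cluster Pre-2 held more markers of another class than of its own among them. GABA-2, GABA-4, GABA-7, GABA-8, Pre-5, RA_Glut-1 and RA_Glut-2 held 0 markers of any class among them, so the check says nothing about their names. Doublets were not removed beyond what the authors did. Scrublet (in scanpy 1.11.5, expected rate 2%) called 8 HVC cells (0.351%) and 17 RA cells (0.929%), and an alternative left them out.

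Shares of cells have exact Clopper-Pearson 95% intervals, a share of 0 has the share of 3 cells as its upper limit, and differences of shares have Newcombe intervals. For expression, UMI counts were summed over the cells of a class and library and divided by the class total to give CPM, counts per 1000000 UMIs of the class. Log2 ratios were taken of CPM + 10. Each ratio of CPM has a 95% interval from the conditional exact binomial distribution of the summed counts, and each CPM an exact Poisson interval. With 1 library per region there is no replicate check, and no p-value was computed. Intervals cover counting error only, not the spread between birds, dissections or droplet runs. Those of expression treat each UMI of a class sum as independent and also leave out the spread between cells. They are too narrow where a few cells hold most UMIs of a gene. A fold against a sum of 0 UMIs was computed against a floor of 3 UMIs in that class sum and is written as at least that fold. Classes were compared only where each library held 30 or more cells, except glutamatergic neurons, whose RA sum holds 17 cells.

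Genes were named by a rule fixed before the data were examined. They needed a CPM of 100 or more, 20 or more UMIs and a UMI in 10% or more of cells in the higher library, and were ranked by the absolute log2 ratio. The 12 highest in each direction were taken for glutamatergic neurons, the 8 highest for GABAergic neurons and the 4 highest for other classes. Mitochondrial, haemoglobin and ribosomal protein genes, locus numbers, and genes under 0.25 of their highest CPM among the classes of that library were left out of naming. Members of the fixed lists were named in addition, by their absolute log2 ratio. A few genes chosen by these rules are not reported here singly or recomputed under the alternatives, and the list values include them. Genes given per cluster, genes named only in the closing section, SLC17A6, CAMK2A, C1QC, TAGLN, FOS in each class and the largest member of a list were chosen after their values were seen.

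Before the data were examined, 43 gene lists with 720 genes were fixed, of which 679 genes are in the table. For a list with 5 or more members at 10 CPM or more, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of expression (seed 1). A list is called outside the limits below percentile 2.5 or above percentile 97.5, which chance gives in 5% of lists of unrelated genes. The percentile describes these libraries and is not a test of the regions. Members counted as higher or lower differed by 2-fold or more on the log2(CPM + 10) scale. The design matched random lists on the mean of both CPMs. In tests on simulated counts that match placed 16.25% of 400 unchanged lists outside the limits for glutamatergic neurons, so it was replaced by the CPM of the pooled sums, which placed 4.75% outside (3% for GABAergic neurons). In the same simulations the interval of the ratio held the true value for 98.07% of 4149 unchanged genes in glutamatergic and 96.81% of 3983 in GABAergic neurons. The interval excluded equality for 22% of 100 genes changed 2-fold and 64% of 100 changed 4-fold in glutamatergic neurons, and for 49% and 89% in GABAergic neurons. The simulations drew each gene as an independent Poisson count, which the interval assumes. They therefore test neither the interval nor the limits of lists for UMIs clustered in few cells or genes expressed together. Their genes were drawn at 50 CPM or more and their lists were of equal size. Measured lists took members from 10 CPM, so the range from 10 to 50 CPM and other list sizes were not tested. Because a class sum of few cells gives 0 UMIs for many genes, each list's median was also computed with sums of 0 set to 3 UMIs, and the UMIs of each list were summed and compared. Both steps were added after the first results were seen.

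The alternatives fixed beforehand were cells of 1000 or more UMIs, Leiden clusters made here (leidenalg 0.10.2, 2000 variable genes, 30 components, 15 neighbours, resolution 1), shares without erythrocytes and vascular cells, removal of Scrublet doublets, the mean over cells of each cell's CPM, thinning to 1000 UMIs of each cell with at least that many, TMM scaling (edgeR 4.0.16 in R 4.3.3), a pseudocount of 1, subtraction of 10% of the library's pooled profile, equal weights for clusters of 10 or more cells, and list minimums of 0 and 50 CPM. Added after seeing the data were the first matching of random lists, totals without mitochondrial and haemoglobin genes, cells of 20% or fewer mitochondrial UMIs, and sums of 0 set to 3 UMIs. The list members recomputed under each alternative, and the pooling of list counts over the non-neuronal classes, were also chosen after a first run. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.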

Results

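The series profiled single cells of HVC and RA of adult male Bengalese finches (Lonchura striata). HVC sends axons to RA, and RA projects to the motor neurons that drive singing. The HVC library held 2278 cells and 2746457 UMIs, with a median of 944 UMIs and 626 genes per cell. The RA library held 1830 cells and 1943197 UMIs, with medians of 837.5 UMIs and 535.5 genes. Of all UMIs, 12.1% in HVC and 11.3% in RA came from haemoglobin genes, and the median mitochondrial share of a cell was 8.94% and 9.64%. Cells under 1000 UMIs numbered 1267 and 1207. There was 1 library per region, so every difference below compares these libraries, and its interval covers counting error only.

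To determine which cell types each dissection yielded, the authors' classes were counted. Glutamatergic neurons made up 27.4% of HVC cells (624 cells, interval 25.6 to 29.3%) and 0.929% of RA cells (17 cells, 0.542 to 1.48%), a difference of 26.5 percentage points (24.6 to 28.4). Oligodendrocyte precursor cells (OPC) went the other way, at 8.47% in HVC (193 cells, 7.36 to 9.69%) and 22.8% in RA (417 cells, 20.9 to 24.8%). Astrocytes made up 2.46% (56 cells, 1.86 to 3.18%) against 13.6% (249 cells, 12.1 to 15.3%), and oligodendrocytes, which form myelin, 5.31% (121 cells, 4.43 to 6.31%) against 12.8% (234 cells, 11.3 to 14.4%). GABAergic neurons held close shares of all cells, 6.15% (140 cells, 5.19 to 7.21%) and 5.79% (106 cells, 4.77 to 6.96%), and the interval of their difference, -1.13 to 1.80 points, included 0. Of the neuronal clusters, however, they made up 14.3% in HVC (12.2 to 16.7%, of 977 cells) and 84.8% in RA (77.3 to 90.6%, of 125 cells). With cells of 1000 or more UMIs the difference of HVC minus RA moved from -11.1 to -1.72 points for astrocytes, from -14.3 to -22.1 for OPC and from -7.48 to -11.4 for oligodendrocytes. With cells of 20% or fewer mitochondrial UMIs that of oligodendrocytes was -0.614.

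Microglia, the resident immune cells of the brain, made up 17.4% of HVC cells (396 cells, 15.8 to 19.0%) and 24.4% of RA cells (447 cells, 22.5 to 26.5%), a difference of -7.04 points that was -12.0 with cells of 20% or fewer mitochondrial UMIs. Endothelial cells made up 14.0% (318 cells, 12.6 to 15.5%) and 9.95% (182 cells, 8.61 to 11.4%). Mural cells, which wrap vessels, held 2.99% (68 cells) and 3.28% (60 cells). Erythrocytes, which are nucleated in birds, held 6.54% (149 cells) and 6.34% (116 cells). Among the astrocyte, oligodendrocyte and OPC cells, OPC held 52.2% in HVC and 46.3% in RA, oligodendrocytes 32.7% and 26%, and astrocytes 15.1% and 27.7%. The dissociation, the sort against DAPI and the depth of a cell can each set which cells were captured, so these are shares of captured cells. Neuronal clusters made up 42.9% of HVC cells (977 cells) and 6.83% of RA cells (125 cells). A larger neuronal share lowers the share of every other class. Lower HVC shares of microglia and other glia among all cells therefore do not by themselves show fewer of them among non-neuronal cells. By the counts above, microglia held the larger share of non-neuronal cells in HVC, the reverse of their order among all cells. OPC, astrocytes and oligodendrocytes held smaller shares of non-neuronal cells in HVC than in RA.

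**Figure D1:**
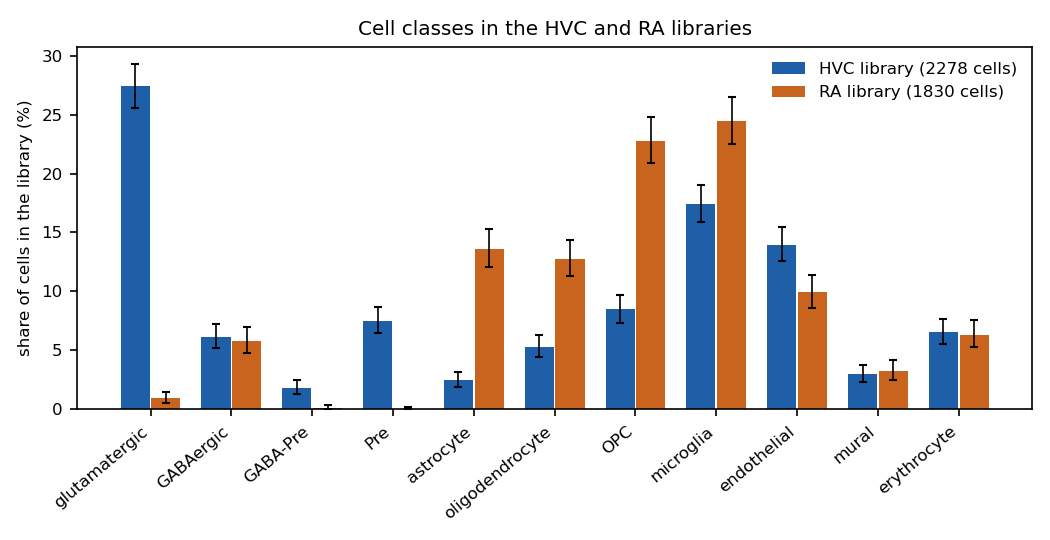
Share of captured cells per class as a percent of all cells of the library, with exact 95% intervals (counting error only), for HVC (2278 cells) and RA (1830 cells). Glutamatergic neurons stand at 27.4% in HVC and 0.929% in RA, OPC at 8.47% and 22.8%, and the error bar of the Pre clusters in RA, with 0 cells, ends at 0.164%, the share of 3 cells.

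Clusters that the authors named Pre or GABA-Pre were found almost entirely in HVC. The Pre clusters held 171 HVC cells (7.51%, 6.46 to 8.67%) and 0 of 1830 RA cells, which allows a share of up to 0.164% (3 cells). GABA-Pre held 42 HVC cells (1.84%, 1.33 to 2.48%) and 2 RA cells (0.109%, 0.0132 to 0.394%). Of the neuronal clusters together, Pre and GABA-Pre made up 21.8% in HVC (19.2 to 24.5%, of 977 cells) and 1.60% in RA (0.194 to 5.66%, of 125 cells). The Pre cells fell into Pre-3 (108 cells), Pre-4 (35), Pre-5 (25) and Pre-2 (3). SOX11, NEUROD1 and STMN1, known from immature neurons, were among the leading genes of Pre-3. With cells of 1000 or more UMIs the difference of HVC minus RA rose from 7.51 to 13.2 points for Pre and from 1.73 to 3.14 for GABA-Pre. A cluster of 1 library may stand for that library and not for a cell type.

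The GABAergic subclasses were then compared within each region. GABA-1 was the largest in both, with 42.1% of HVC (59 cells) and 36.8% of RA GABAergic neurons (39 cells). GABA-2, led by NPY and SST, made up 32.9% (46 cells, 25.2 to 41.3%) and 18.9% (20 cells, 11.9 to 27.6%). GABA-5, led by the opioid precursor PENK and by CRH, made up 8.57% (12 cells, 4.51 to 14.5%) and 26.4% (28 cells, 18.3 to 35.9%), a difference of -17.8 points. GABA-6, led by CRTAC1, had 1 HVC and 9 RA cells, a difference of -7.78 points that was -14 with cells of 1000 or more UMIs and -0.576 with 20% or fewer mitochondrial UMIs, and GABA-3, led by VIP, 14 (10.0%) and 8 (7.55%). Of the glutamatergic cells, HVC_Glut-1 held 297 (47.6%), HVC_Glut-2 244 (39.1%), HVC_Glut-3 53, HVC_Glut-4 26 and HVC_Glut-5 4, while all 17 RA cells lay in RA_Glut-1 (15) or RA_Glut-2 (2).

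To determine how projection neurons of HVC differ from those of RA, summed UMIs of the glutamatergic clusters were compared, HVC_Glut-1 to HVC_Glut-5 on one side and RA_Glut-1 and RA_Glut-2 on the other. CAMK2N1, an inhibitor of the kinase CaMKII, had 1577 UMIs in HVC (2368 CPM) and 1 in RA, a ratio of HVC over RA of 66.5 (11.9 to 2630). The calcium pump ATP2A3 had 447 against 0 (at least 6.29-fold), TUSC5 333 against 0 (at least 4.68-fold) and the ephrin receptor EPHA3 294 against 0 (at least 4.14-fold). Of the genes higher in RA, the adhesion molecule CHL1 was 4.66-fold higher (3.17 to 6.69; 183 UMIs in HVC, 36 in RA), the contactin CNTN4 3.95-fold (2.36 to 6.30; 126 and 21), the receptor phosphatase PTPRD 3.6-fold (2.19 to 5.65; 145 and 22) and LSAMP 3.52-fold (2.55 to 4.76; 330 and 49). The list of cadherins and protocadherins lay inside the limits of random lists and toward HVC (18 measured, median log2 1.03, percentile 89.9, 10 higher and 1 lower by 2-fold), but 7 members had 0 RA UMIs, and with those sums set to 3 UMIs the median was -0.32 (percentile 24.8).

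Other genes with 0 RA UMIs were HLF, a transcription factor of the PAR bZIP family (222 HVC UMIs, at least 3.12-fold), LRRC4C, a netrin-G ligand (198, at least 2.79-fold), LMO1 (196, at least 2.76-fold), PLCL2 (195, at least 2.74-fold), the ephrin receptor EPHA7 (190, at least 2.67-fold), MGAT5 (187, at least 2.63-fold) and the kinase CAMK1D (186, at least 2.62-fold). In the RA library the microtubule protein MAP1B was 2.97-fold higher (2.23 to 3.91) and the cadherin CDH6 2.87-fold (1.71 to 4.58). FBXO34 was 2.43-fold, KIAA1211 2.05-fold, the calcium buffer PVALB 2.04-fold (1.39 to 2.90), ATP5J2 2.0-fold and KMT2C 1.97-fold higher there. Because the authors clustered the same cells, ATP2A3, a leading gene of HVC_Glut-4, and CNTN4, CHL1, PTPRD and PVALB, leading genes of RA_Glut-1 or RA_Glut-2, describe those clusters. The RA sum held 28103 UMIs against 665955 in HVC, so that 1 RA UMI is worth 35.6 CPM, and its cells had a median mitochondrial share of 28.8% against 14.3%. Of the summed UMIs, 27.2% in RA and 13.9% in HVC were mitochondrial, which lowers the CPM of all other genes more in RA. Over genes at a pooled 10 CPM or more the median log2 of HVC over RA was 0.47. A ratio of 1 or a log2 of 0 is therefore not the middle of this comparison.

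**Figure D2:**
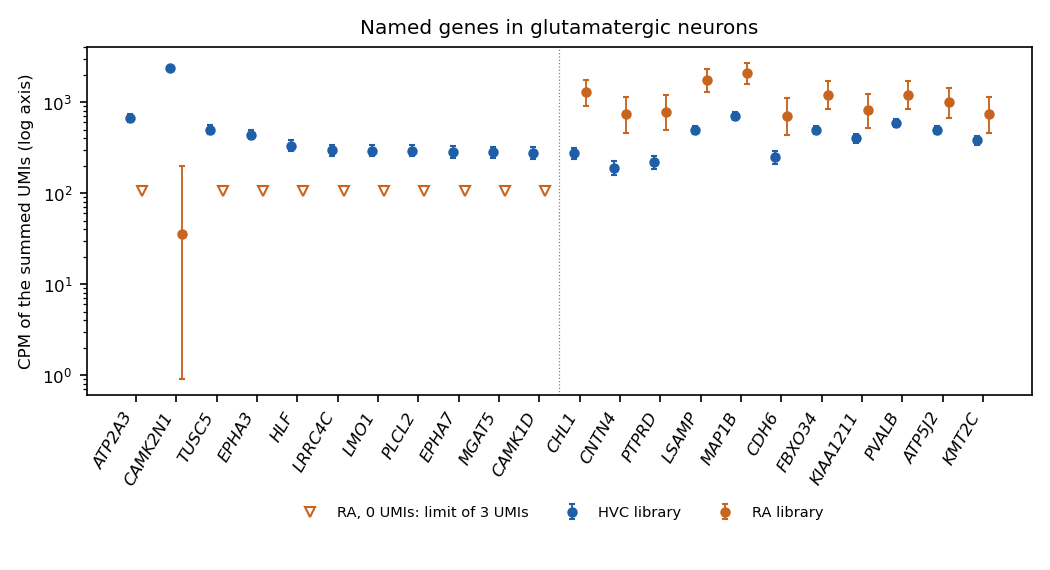
CPM (log axis) of the named genes in the summed glutamatergic cells of HVC (624 cells) and RA (17 cells), with exact Poisson 95% intervals. Triangles mark genes with 0 RA UMIs at the limit of 3 UMIs, and CHL1 (4.66-fold) has the largest fold of the plotted genes on the RA side.

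Of 32 lists measured in glutamatergic neurons, 7 lay outside the limits on the HVC side and 3 on the RA side. With sums of 0 set to 3 UMIs these counts were 1 and 6, and with the mean of each cell's CPM 2 lay on the HVC side. Markers of glutamatergic neurons were higher in HVC (5 measured, median log2 1.86, percentile 98.5, 4 higher and 0 lower by 2-fold), with TBR1, a transcription factor of pallial projection neurons, at a ratio of 6.35 (1.74 to 52.7), the plasticity gene NRN1 at 9.68 (2.67 to 80.2), the vesicular glutamate transporter SLC17A6 at 3.76 (1.71 to 10.3) and the kinase CAMK2A at 1.55 (1.10 to 2.26). Genes of perineuronal nets and the extracellular matrix had a median of 1.58 (8 measured, percentile 97.9, 5 higher, 0 lower), with SPOCK1, a proteoglycan, at 485 against 1 UMI (20.5, 3.66 to 810) and PTPRZ1 at 178 against 0 (at least 2.50-fold). With sums of 0 set to 3 UMIs the markers kept their median of 1.86, whereas the matrix genes had 0.23 (percentile 90.4), and their summed UMIs were 3.94-fold higher in HVC (2.29 to 7.42).

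The other HVC-side lists rested on members with few or 0 RA UMIs. Candidate genes of song projection neurons (16 measured, median 1.66, percentile 100, 12 higher, 1 lower) included the peptide NTS at 833 against 2 UMIs (17.6, 4.85 to 145) and, on the RA side, PVALB. With sums of 0 set to 3 their median was -0.41, and the ratio of their summed UMIs was 1.67 (1.29 to 2.20), or 1.11 (0.856 to 1.48) without NTS. Neuropeptides (12 measured, 1.42, 99.4, 7 higher, 3 lower) held NTS and the granin CHGB (549 against 3 UMIs, 7.72, 2.63 to 37.6) on the HVC side and ADCYAP1, the peptide PACAP, on the RA side (118 against 17 UMIs, 3.41-fold higher in RA, 1.92 to 5.70). Their median was -0.24 with sums of 0 at 3, while the ratio of their summed UMIs was 1.87 (1.43 to 2.48), or 1.28 (0.980 to 1.72) without NTS. Markers of intratelencephalic upper-layer neurons of mammals (10 measured, 1.96, 98.4, 6 higher, 2 lower) included MEF2C (338 against 1 UMI, 14.3, 2.54 to 565) and RASGRF2 (125 against 0, at least 1.76-fold), and their median became -0.96 with a ratio of summed UMIs of 2.25 (1.34 to 4.14), or 1.33 (0.770 to 2.52) without MEF2C. Axon guidance genes (25 measured, 1.14, 98.4, 13 higher, 4 lower), EPHA3 and EPHA7 among them, became -0.21 with a ratio of summed UMIs of 1.02 (0.818 to 1.29). Genes of interneurons from the medial ganglionic eminence, MGE (7 measured, 1.53, 97.7, 5 higher, 1 lower), among them SST (81 against 1 UMI, 3.42, 0.596 to 137), became -0.74 with a ratio of 0.743 (0.589 to 0.951). In RA 3 UMIs are 107 CPM, so a member at 0 UMIs there turns toward RA wherever HVC has less. With sums of 0 at 3 the percentiles were 23.6 for song projection candidates, 13.45 for neuropeptides, 4.66 for upper-layer markers and 36.3 for axon guidance. All of these lay inside the limits, so their medians below 0 show no turn to RA. MGE genes were at percentile 1.415, outside on the RA side.

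On the RA side stood microglial activation and antigen presentation genes (8 measured, median -1.23, percentile 0, 0 higher and 4 lower in HVC), with a ratio of summed UMIs of 0.531 (0.441 to 0.644). CD74, the invariant chain of MHC class II, was 4.53-fold higher in RA (2.30 to 8.27), B2M 3.39-fold and the ferritin FTH1 1.78-fold. Myelin and lipid synthesis genes had a median of -0.64 (20 measured, percentile 0.07, 5 higher, 8 lower in HVC) and a ratio of summed UMIs of 0.730 (0.551 to 0.984), with UGT8 4.51-fold higher in RA on 21 against 4 UMIs. Glutamate receptors had a median of -0.14 (25 measured, percentile 1.11, 7 higher, 3 lower in HVC), with GRIK1 at 1 against 7 UMIs (166-fold higher in RA, 21.3 to 7476) and GRM3 at 45 against 7 (3.69-fold, 1.40 to 8.23). Their summed UMIs had a ratio of HVC over RA of 1.01 (0.891 to 1.14), or 1.22 (1.04 to 1.43) without GRIA2. The larger mitochondrial share of the RA sum raises this ratio for all other genes, so 1.22 is not read as a lean toward HVC. With cells of 20% or fewer mitochondrial UMIs, which left 6 RA cells, the receptor median became 0.78.

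To determine whether interneurons differ between the regions, the GABAergic clusters were compared (178857 UMIs in HVC, 126619 in RA). Their cells had a median mitochondrial share of 11.3% in HVC and 14.3% in RA, and of the summed UMIs 9.71% and 15.9% were mitochondrial. Neuropeptide genes separated the libraries in both directions. GRP, gastrin-releasing peptide, was 41.1-fold higher in HVC (11.1 to 343; 116 against 2 UMIs), and the calcium buffer CALB2 5.01-fold (2.73 to 10.1; 85 against 12). In RA, PENK was 6.93-fold higher (5.71 to 8.47; 125 UMIs in HVC, 613 in RA), CRH 6.22-fold (3.08 to 13.9; 10 and 44), the chemokine CXCL14 8.14-fold (4.83 to 14.5; 17 and 98) and the granin SCG2 3.44-fold (2.92 to 4.07; 204 and 497). CNR1, the cannabinoid receptor, was 3.38-fold higher in RA (2.64 to 4.37) and CRTAC1 38.1-fold (1 against 27 UMIs, 6.29 to 1561.5).

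Further genes higher in the HVC library were the transcription factor SOX1 (10.6-fold, 2.69 to 91.7), RASL11A (9.20-fold), NKAIN3 (8.85-fold), RSL24D1 (5.90-fold), SH3BP5 (5.66-fold, 2.42 to 16.2) and the GTPase RAC1 (5.66-fold). In RA, the synaptotagmin SYT13 was 5.65-fold and GDPD5 4.52-fold higher. PENK, CRH, CNR1 and SCG2 lead GABA-5, CRTAC1 leads GABA-6, GRP is a leading gene of GABA-2 and CALB2 leads GABA-7 (5 HVC and 0 RA cells), so these values follow in part the shares of those clusters. Of the 85 HVC UMIs of CALB2, 33 came from 2 GABA-5 cells. Of the HVC UMIs, 15 of 30 for SOX1 and 29 of 48 for SH3BP5 came from 16 HVC cells with 7% or more ribosomal protein UMIs and 5% or fewer mitochondrial UMIs, as did 2 of 116 for GRP.

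**Figure D3:**
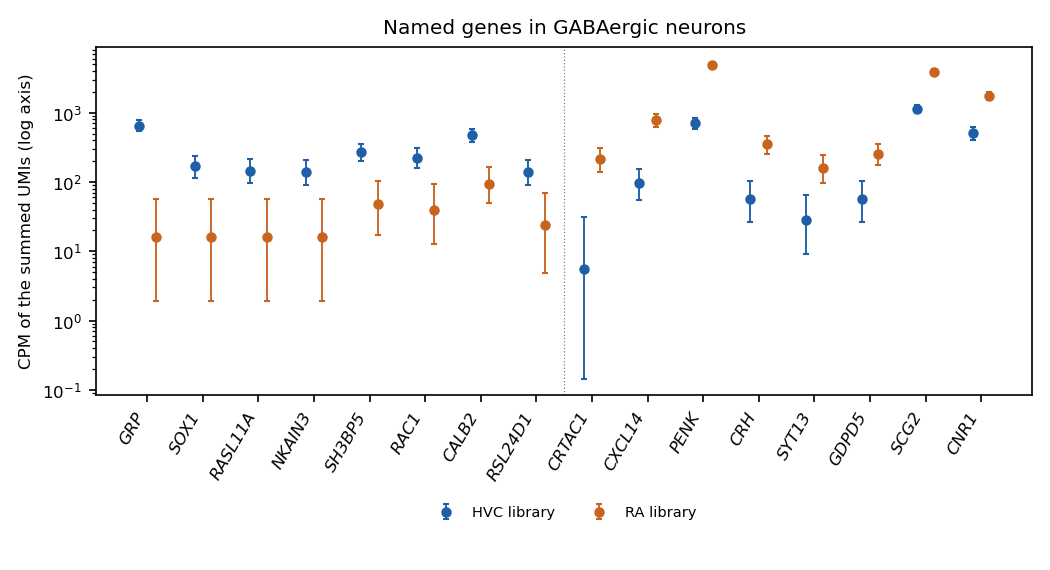
CPM (log axis) of the named genes in the summed GABAergic neurons of HVC (140 cells) and RA (106 cells), with exact Poisson 95% intervals. GRP (41.1-fold) has the largest fold of the plotted genes on the HVC side, and CRTAC1, CXCL14 and PENK have the largest on the RA side.

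Within clusters, the shares of cells with a UMI differed beyond their intervals for VIP and CXCL14, and those of GRP, SST, NPY and CRH had overlapping intervals. VIP had 118 UMIs in RA GABA-3, in 5 of 8 cells (62.5%, 24.5 to 91.5%; median depth 1084 UMIs), and 0 UMIs in the 14 HVC GABA-3 cells (up to 21.4%, 3 cells; 880.5 UMIs), whereas 2 of 447 RA microglia (0.447%, 950 UMIs) and 0 of 396 HVC microglia (1052 UMIs) had a VIP UMI. GRP had 110 UMIs in 8 of 46 HVC GABA-2 cells (17.4%, 7.82 to 31.4%; 1429.5 UMIs) and 0 in 20 RA GABA-2 cells (up to 15%, 3 cells; 1033.5 UMIs), with 0 of 396 HVC and 1 of 447 RA microglia. CXCL14 was found in 15 of 20 RA GABA-2 cells (75%, 50.9 to 91.3%) and 3 of 46 HVC cells (6.52%, 1.37 to 17.9%), against 2.27% of HVC and 1.57% of RA microglia. PENK was found in all 12 HVC GABA-5 cells (89 UMIs) and in 27 of 28 RA cells (597 UMIs), against 0.505% of HVC and 2.91% of RA microglia. SST was found in 71.7% of HVC and 75% of RA GABA-2 cells (microglia 2.78% and 2.01%), NPY in 65.2% and 80% (1.52% and 0.447%), and CRH in 33.3% and 39.3% of GABA-5 cells (0 of 396 and 2 of 447 microglia; median depth 675.5 and 943.5 UMIs). In GABA-1, compared as a sum (59 and 39 cells), YBX1 was 5.05-fold (1.82 to 19.5), SERPINE2 6.38-fold, SPEN 5.58-fold and POLR2D at least 3.55-fold higher in HVC. The histone gene H2B-VII was 7.35-fold (3.73 to 15.8), SCG2 2.48-fold (1.85 to 3.32), SV2A 2.33-fold and NR2F1 2.23-fold higher in RA. Its lists outside the limits were ribosomal proteins (0.48) and corticofugal markers (0.90) toward HVC and oligodendrocyte markers (-1.19) and upper-layer markers (-0.73) toward RA. These 2 and 2 lists became 0 and 5 with the mean of each cell's CPM, and 1 and 0 with sums of 0 at 3 UMIs, where the ribosomal proteins stayed outside.

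Of 34 lists in GABAergic neurons, 3 lay outside the limits on the HVC side and 10 on the RA side, against 1 on the HVC side with the mean of each cell's CPM and 6 on the RA side with thinning. Genes of interneurons from the caudal ganglionic eminence, CGE, were higher in RA (11 measured, median -1.10, percentile 0, 1 higher and 7 lower in HVC), with VIP at least 56.0-fold (0 against 119 UMIs), PROX1 3.30-fold (1.62 to 7.12) and ADARB2 2.76-fold (1.59 to 4.91), while CALB2 went the other way. Neuropeptides had a median of -0.65 (16 measured, percentile 0, 4 higher, 6 lower), with CRHBP 4.61-fold higher in RA (3.41 to 6.32). Perineuronal net and matrix genes had -0.70 (9 measured, percentile 0.02, 0 higher, 2 lower), with RELN 1.97-fold higher in RA (1.41 to 2.77). MGE genes had -0.35 (11 measured, percentile 1.89, 3 higher, 2 lower), with SATB1 at 1 against 15 UMIs and SOX6 2.83-fold higher in HVC, and 0.20 with clusters weighted equally. Potassium channels had -0.28 (34 measured, percentile 0.545, 2 higher, 7 lower), with KCNC2 2.17-fold higher in RA, and 0.12 with the mean of each cell's CPM.

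Ribosomal protein genes were higher in HVC (23 measured, median 1.33, percentile 100, 18 higher and 0 lower), with RPS2 10.2-fold (4.78 to 26.1) and RPL11 4.10-fold. Without the 16 HVC cells picked for a high ribosomal share the median was 0.50 (percentile 99.97), a fall that such a pick brings in itself. Immediate early genes had 0.50 (18 measured, percentile 97.7, 4 higher, 0 lower), with NR4A1 at 23 against 0 UMIs (at least 5.43-fold), ARC 2.49-fold (1.52 to 4.27) and FOS 1.96-fold (1.5 to 2.59), and 0.31 (percentile 91.92) without those cells. Markers of other cell types differed too: microglial markers were higher in HVC GABAergic cells (5 measured, median 1.08, percentile 99.0, 3 higher and 0 lower; CD74 4.33-fold, 2.12 to 9.96), although microglia held the larger share of all cells in RA. Higher in RA, where these glia held larger shares of all cells, were astrocyte markers (8 measured, -1.17, 0 higher, 6 lower; SLC1A3 7.06-fold, 2.37 to 28.4) and oligodendrocyte markers (5 measured, -1.30, 0 higher, 3 lower; MBP 2.64-fold, 1.36 to 5.31). Other RA-side lists were astrocyte function (21 measured, -0.65, 0 higher, 6 lower; GLUL 2.25-fold higher in RA), myelin and lipid synthesis (22 measured, -0.39, 2 higher, 3 lower) and upper-layer markers (8 measured, -0.44, 0 higher, 1 lower, or 0.32 with thinning to 1000 UMIs). With sums of 0 at 3 UMIs all 13 lists kept their side of the limits.

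**Figure D4:**
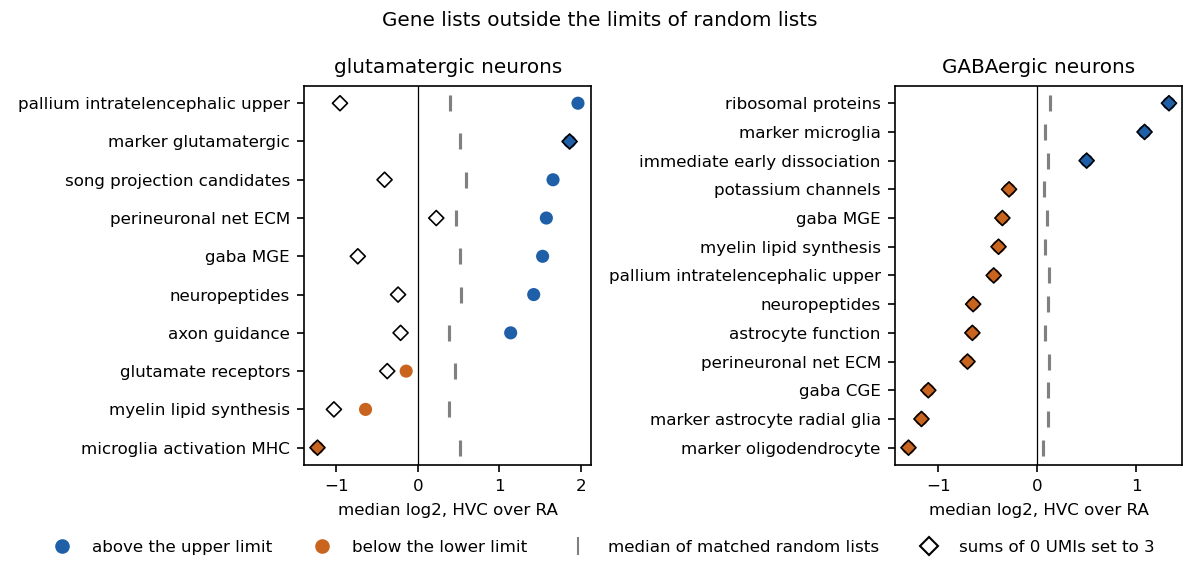
Median log2 ratio (HVC over RA) of each gene list outside the limits of 10000 random lists in glutamatergic and GABAergic neurons, with grey bars at the median of the random lists and open diamonds with sums of 0 UMIs set to 3. In glutamatergic neurons the diamonds of 5 lists that lie on the HVC side fall below 0, for example song projection candidates from 1.66 to -0.41, and in GABAergic neurons the medians keep their sign. Those 5 diamonds rest on the 3 UMIs (107 CPM) put for 0 in RA, and only MGE genes then lie outside the limits (percentile 1.415).

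To determine regional differences of glia and vessels, each non-neuronal class was compared in the same way. GFAP, the astrocyte intermediate filament, was 16.5-fold higher in RA astrocytes (1 against 64 UMIs, 2.86 to 662), and the homeobox gene MEIS2 at least 2.58-fold, the endothelin receptor EDNRA at least 2.24-fold and ATP9B at least 2.15-fold. PROCA1 was 6.16-fold (3.24 to 12), LRP1 3.05-fold, ARL6IP1 2.58-fold and the proteoglycan CSPG5 2.34-fold (1.71 to 3.17) higher in HVC astrocytes. In mural cells the smooth muscle genes MYH11 (1 against 23 UMIs) and ACTA2 (1 against 20) were 28.9-fold (4.70 to 1192) and 25.2-fold (4.03 to 1043) higher in RA, while IMPA2 (19.1-fold), SRSF5 (8.74-fold), ABLIM1 (7.15-fold) and SPON1 (5.30-fold) were higher in HVC. ITIH5 (6.40-fold) and COCH (5.20-fold, 3.83 to 7.19) were also higher in RA mural cells, but lay mostly in 11 RA and 3 HVC mural cells that clusters made here called fibroblast-like, the other mural cells holding 2 RA and 2 HVC UMIs of ITIH5 and 13 and 2 of COCH. In those other mural cells TAGLN, another smooth muscle gene, had 21 UMIs in RA and 18 in HVC, unlike MYH11 and ACTA2. In microglia, TNFRSF25 was 4.79-fold (2.54 to 9.81), the transcription factor BHLHE40 2.86-fold (2.28 to 3.61), ID2 3.10-fold (2.19 to 4.46) and the sterol transporter ABCG1 3.18-fold higher in HVC. The stress gene DDIT4 was 4.01-fold (2.61 to 6.35), CITED2 2.58-fold (1.98 to 3.40), KLHL6 2.44-fold and ZNF710 2.44-fold higher in RA microglia.

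In endothelial cells, UAP1 was 6.25-fold, the peptide EDN2 4.90-fold (1.97 to 15.7), the immediate early gene EGR2 3.70-fold (2.45 to 5.80) and USP37 3.71-fold higher in HVC, and ZMYND8 4.16-fold (a log2 of 0.076, toward HVC, with thinning), PHF3 3.01-fold, HSPA4L 2.94-fold and ERGIC3 2.84-fold higher in RA. In OPC, the cAMP-responsive factor CREM was 3.30-fold (2.27 to 4.81), SLC6A17 3.48-fold, FGGY 3.24-fold and ATRIP 2.93-fold higher in HVC, and RNPEPL1 3.97-fold (2.08 to 8.51), POLR3K 3.78-fold, PYURF 3.46-fold and UBE2N 3.01-fold higher in RA. In oligodendrocytes, IFRD1 was 3.59-fold, EPCAM 3.11-fold, MED28 3.11-fold and HSBP1 2.82-fold higher in HVC, and MLEC 5.27-fold, NOVA1 5.81-fold, TMX2 4.88-fold and SGCB 3.37-fold higher in RA.

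Immediate early genes were above the limits toward HVC in 5 of these classes. In endothelial cells the median was 0.61 (19 measured, percentile 100, 5 higher, 0 lower), with NR4A1 2.88-fold (2.09 to 4.06), FOSL2 3.29-fold (2.02 to 5.64) and BTG2 2.36-fold (1.97 to 2.85) higher in HVC. Astrocytes had 0.81 (16 measured, 8 higher, 1 lower), OPC 0.37 (19 measured, 3 higher, 0 lower, with NR4A1 2.36-fold, 1.90 to 2.93), mural cells 0.42 and microglia 0.18 (19 measured, 1 higher, 2 lower). In microglia the mean of the list was -0.048 and the ratio of its summed UMIs 0.902 (0.873 to 0.932), both toward RA. FOS itself had a ratio of HVC over RA of 1.27 (1.15 to 1.40) in endothelial cells, 1.29 (1.20 to 1.40) in OPC and 0.25 (0.199 to 0.312) in microglia. The median in microglia was -0.16 with a list minimum of 50 CPM.

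Further lists outside the limits included markers of other cell types. Toward HVC, oligodendrocytes had neuron markers at 1.77 (8 measured, 6 higher, 0 lower; SNAP25 6.45-fold, 2.64 to 18.0), synaptic vesicle genes at 1.01 and ribosomal proteins at 0.31 (-0.057 with 20% or fewer mitochondrial UMIs), and astrocytes had synaptic vesicle genes at 1.30. Endothelial cells had neuron markers at 0.99 toward HVC and astrocyte markers at -1.15 toward RA, and microglia astrocyte markers at -0.48 and astrocyte function at -0.41 (0.38 with 10% of the pooled profile subtracted). Microglial activation genes were higher in HVC microglia (17 measured, 0.26, percentile 99.8, 4 higher, 0 lower), with the lectin LGALS3 3.76-fold (1.48 to 11.3) and CD63 1.43-fold. In OPC, ribosomal proteins (-0.45) and oxidative phosphorylation genes (-0.37) stood toward RA, as did the latter in astrocytes (-0.29, or 0.10 with thinning). Genes of the dorsal ventricular ridge and amygdala were lower in HVC astrocytes (11 measured, -1.41, percentile 0, 0 higher, 6 lower; EMX2 at 1 against 32 UMIs), with a median of -0.30 at sums of 0 set to 3 (percentile 7.04, inside the limits). Matrix genes stood toward RA in oligodendrocytes (-0.64) and microglia (-0.72). In oligodendrocytes they had -0.31 with sums of 0 at 3 (percentile 3.18, inside the limits) and 0.15 with 10% of the pooled profile subtracted, and in microglia 0.19 with thinning. In mural cells axon guidance genes (-0.78, or 0.19 and percentile 65.6 with sums of 0 at 3) and fibroblast markers (-1.41; 8 measured, 0 higher, 4 lower; COL1A1 0 against 11 UMIs, at least 4.61-fold higher in RA) stood toward RA. The fibroblast-like cells held all 11 of these COL1A1 UMIs, and the fibroblast markers had -0.63 with sums of 0 at 3 and a ratio of summed UMIs of 0.766 (0.600 to 0.978). Over all 9 comparisons of HVC with RA, 39 of 285 list values lay outside on the HVC side and 31 on the RA side, where chance gives 5% in all for lists of unrelated genes.

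Glutamatergic and GABAergic neurons were also compared within each library, with markers of the classes serving only as a check of their names. In that check glutamatergic markers stood at 3.89 in HVC and 1.35 in RA, and GABAergic markers at -4.33 and -4.92. With sums of 0 at 3 UMIs the glutamatergic markers in RA had 1.27 at percentile 66.0, inside the limits. The GABAergic markers in RA, with 7 of 8 members at 0 glutamatergic UMIs, then had -1.87 (percentile 0.06). In HVC, neuropeptides were lower in glutamatergic neurons (14 measured, -1.40, 3 higher, 8 lower), with NPY 105-fold (47.2 to 290) and CRHBP 70.7-fold higher in GABAergic neurons, while NTS was 14.0-fold (8.56 to 24.6) and ADCYAP1 at least 10.6-fold higher in glutamatergic neurons. Potassium channels were higher in glutamatergic neurons (34 measured, 0.65, percentile 99.98, 12 higher, 5 lower), with KCNA4 at least 2.69-fold and KCNIP4 5.55-fold (1.81 to 27.6), the latter turning to a log2 of -0.19 with clusters weighted equally. Immediate early genes were lower there (19 measured, -1.06, 2 higher, 10 lower), with FOS 4.60-fold (3.73 to 5.68) and EGR1 3.43-fold higher in GABAergic neurons. Ribosomal proteins stood at -1.18 (23 measured, 0 higher, 18 lower), but at 0.0017 within RA (percentile 90.4, inside the limits). The HVC GABAergic sum includes the 16 cells of high ribosomal share. Neither the ribosomal nor the immediate early list was computed within HVC without them. Steroid hormone genes stood at 0.99 in HVC (10 measured, 5 higher, 1 lower; NR3C2 3.8-fold, 1.68 to 10.7), or -0.016 with sums of 0 at 3.

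In RA, corticofugal markers were higher in glutamatergic neurons (13 measured, median 1.35, percentile 99.99, 7 higher, 1 lower), with the transcription factors SOX5 6.76-fold (1.60 to 32.6) and ETV1 5.73-fold (2.42 to 14.0), and they had 1.27 with sums of 0 at 3. Neuropeptides had 56 UMIs in glutamatergic and 2223 in GABAergic neurons, a ratio of 0.114 (0.0855 to 0.148; 17 measured, median -3.48, or -0.31 and percentile 17.6, inside the limits, with sums of 0 at 3), with PENK 136-fold (24.3 to 5383), NPY at least 11.3-fold and VIP at least 8.80-fold higher in GABAergic neurons. Perineuronal net and matrix genes had a ratio of summed UMIs of 0.169 (0.0890 to 0.292; 9 measured, median -3.63, or -1.48 with sums of 0 at 3), with RELN at least 6.51-fold and TNR at least 2.15-fold higher in GABAergic neurons. Microglial markers were higher in RA glutamatergic neurons (6 measured, 1.64, 6 higher, 0 lower), with the complement gene C1QC 22.5-fold (4.80 to 211) on 10 against 2 UMIs. Axon guidance genes had a median of -1.37 (16 of 28 members with 0 glutamatergic UMIs), or 0.84 with sums of 0 at 3, and a ratio of summed UMIs of 0.853 (0.665 to 1.08). All 5 OPC markers had 0 glutamatergic UMIs, against 61 in GABAergic neurons.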

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

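All tests in this part were chosen after the result was seen, except that of depth behind the immediate early genes, whose prediction was written before.

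Several values of glutamatergic over GABAergic neurons pointed in opposite directions in the HVC and RA libraries, and the difference itself was not tested. Of 378 list genes measured in both libraries, 22 had intervals on opposite sides of equality. Microglial markers stood at a median log2 of -1.25 in HVC (percentile 0.23) and 1.64 in RA (percentile 99.85), with C1QC at -2.16 and 3.83 and CD74 at -1.50 and 2.54. ETV1, a transcription factor of corticofugal neurons in mammals, stood at -1.31 in HVC and 2.39 in RA (14 glutamatergic against 11 GABAergic UMIs). LDB2, a marker of the same neurons, stood at -2.28 and 2.18, the RA value on 4 against 3 UMIs. The whole list of corticofugal markers did not turn in this way. It stood at -0.063 in HVC (percentile 32.55, inside the limits, 14 measured, 5 higher, 5 lower) and at 1.35 in RA (percentile 99.99). Candidate genes of song projection neurons stood at 0.78 in HVC (percentile 99.89, or 97.1 and inside the limits with sums of 0 set to 3) and -2.31 in RA (percentile 0.01), but in RA 9 of the 15 measured members had 0 glutamatergic UMIs, and the RA median is 1.24 with sums of 0 set to 3, while their summed UMIs (59 against 391) had a ratio of 0.680 (0.508 to 0.896), or 1.30 (0.954 to 1.74) without CRHBP. Of the 4110 deposited cells, 2 carried the region name arco and lay outside every comparison: a cell of the microglia cluster with 697 UMIs and a cell of the erythrocyte cluster with 809 UMIs.

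The RA library held 17 glutamatergic cells against 624 in HVC. Clusters made here named 14 RA cells glutamatergic, so they found no surplus placed in other clusters. They used the same counts and gave 96.2% of all cells the authors' class (GABA-Pre taken as GABAergic), so they cannot exclude such placement. Loss of shallow RA cells to the authors' filter stays open, since the deposited cells (median 1447 UMIs in RA, 946.5 in HVC) are those that passed it. Glutamatergic markers in classes other than neurons, where they can come from free RNA, had a ratio of RA over HVC of 0.359 (0.278 to 0.460; 92 against 218 UMIs), well above the ratio of 0.0596 between the libraries' shares of UMIs in glutamatergic cells. This is consistent with RA projection neurons lost before capture, although low expression of these markers in glia would give the same. A true difference in the share of glutamatergic neurons between the regions was not tested and stays open.

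Ribosomal protein genes were higher in HVC than in RA GABAergic neurons, with a median log2 of 1.33. In 16 HVC cells (4 of GABA-1, 12 of GABA-2) with 7% or more ribosomal and 5% or fewer mitochondrial UMIs, thresholds set after viewing the cells, immature neuron markers were 4.40-fold higher (3.81 to 5.09) than in the other 124 HVC cells, so immature cells may hold part of the pattern. Their median depth was 2604.5 against 942 UMIs. RA had 1 such cell, which was kept, and without the 16 HVC cells the median was still 0.50. Leaving out cells picked by their ribosomal share lowers the median in itself, so the fall says nothing on immature cells. Microglial markers in the 16 cells reached 1.87% (1.13 to 2.92%) of their level in HVC microglia, which argues against microglial RNA in those cells only. They summed to 462 CPM there and 588 CPM in the other 124 HVC cells, where microglial RNA was not tested. With mitochondrial and haemoglobin genes out of the total the median was 1.24, so the mitochondrial share of the total holds little of the pattern. That shift is set by the summed mitochondrial shares (9.71% in HVC, 15.9% in RA) and speaks only to their effect on the total. A regional difference in the remaining cells was not tested and stays open.

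The median of the immediate early genes lay above the limits toward HVC in 6 of the 8 classes compared, but in microglia their summed UMIs leaned to RA (0.902, 0.873 to 0.932), and in GABAergic neurons the list fell inside the limits (percentile 91.92) without the 16 cells of high ribosomal share. Free RNA shared by all classes predicted a higher FOS in each HVC class. In microglia FOS had a ratio of HVC over RA of 0.25 (0.199 to 0.312), against that prediction. HVC microglia held 237 CPM of FOS, below the excess over RA in OPC (1135), endothelial (1104), mural (1739) and GABAergic cells (562) and astrocytes (369). The excess was 59.9 CPM in oligodendrocytes, and glutamatergic neurons had a ratio of 0.584 (0.325 to 1.15). How much free RNA raised the whole list in any class was not tested and stays open. Deeper HVC cells do not account for the higher list in the endothelial cells of 1000 or more UMIs (90 of 318 in HVC, 24 of 182 in RA), where the list was at percentile 99.3 (median 0.53) with each cell thinned to 1000 UMIs. Handling that differed between the tissues and a difference of the regions in the birds cannot be told apart, because each region was 1 library. Pronase at 37 °C can itself induce these genes, and both tissues received it.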

How the results depend on the processing

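The settings with sums of 0 at 3 UMIs, 20% or fewer mitochondrial UMIs, totals without mitochondrial and haemoglobin genes, and the first matching of random lists were chosen after the data were seen. No paired analysis was possible because both regions have 1 library each, numbered replicate 1, and no cell is assigned to a bird. Of the alternatives tried, 37 of 51 class shares, 32 of 36 neuron type shares and 1978 of 2073 gene values stayed within their interval and on their side, and 995 of 1189 list values kept their side of the limits, with 174 inside them and 20 past the middle of the random lists. Under every alternative, 14 of 70 lists between the regions and 11 of 29 within a library kept their side. The median of all genes (log2) moved by over 0.1 in glutamatergic neurons with thinning (0.40), TMM (0.24), totals without mitochondrial and haemoglobin genes (-0.19) and 20% or fewer mitochondrial UMIs (1.02), in astrocytes with TMM (-0.19), in oligodendrocytes with thinning (-0.13) and TMM (-0.12), in endothelial cells with thinning (0.12), and within RA with thinning (0.10), TMM (-0.30), those totals (0.16) and 20% or fewer mitochondrial UMIs (-1.31). List percentiles are relative to that median. Few cells limit the settings: thinning left 263 HVC and 15 RA glutamatergic cells, 7 and 15 astrocytes and 5 and 1 mural cells, and 20% or fewer mitochondrial UMIs left 512 and 6 glutamatergic cells. Fewer cells or genes enter several settings by construction, and otherwise the cause was not tested.

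Differences of shares are HVC minus RA in percentage points. With cells of 1000 or more UMIs they were 23.6 for glutamatergic neurons, 3.14 for GABA-Pre, 13.2 for Pre, -1.72 for astrocytes, -11.4 for oligodendrocytes, -22.1 for OPC, -2.17 for erythrocytes and -14 for GABA-6. With clusters made here the glutamatergic difference was 28.5. Without erythrocytes and vascular cells it was 34.6, that of Pre 9.81, of astrocytes -13.7 and of OPC -17.3. With 20% or fewer mitochondrial UMIs oligodendrocytes had -0.614, microglia -12.0 and GABA-6 -0.576, and RA_Glut-1 held 100% and RA_Glut-2 0% of RA glutamatergic cells.

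Other values are log2 ratios or counts of lists outside the limits. With 20% or fewer mitochondrial UMIs GPNMB in glutamatergic neurons had 1.05 (main value -1.88), glutamate receptors there 0.78 and ribosomal proteins in oligodendrocytes -0.057, and the lists numbered 3 (of 7) on the HVC side in glutamatergic neurons and 6 (of 10) on the GABAergic side within RA. With thinning GPNMB had 1.10, upper-layer markers in GABAergic neurons 0.32, CTSS -1.58 (1.08) and CNP 0.40 (-0.80) in GABAergic neurons, oxidative phosphorylation in astrocytes 0.10, matrix genes in microglia 0.19 and ZMYND8 0.076. The rule then kept 2 (of 4) genes named in HVC astrocytes and 0 (of 4) in RA mural cells, and lists numbered 5 (of 3) on the RA side in glutamatergic neurons, 6 (of 10) in GABAergic neurons, 15 (of 27) and 6 (of 16) on the HVC and RA sides in non-neuronal classes and 1 (of 2) on the RA side in GABA-1. With the mean of each cell's CPM potassium channels in GABAergic neurons had 0.12, and lists numbered 2 on the HVC side in glutamatergic neurons, 1 (of 3) in GABAergic neurons, and 0 and 5 on the HVC and RA sides in GABA-1. With equal clusters MGE genes in GABAergic neurons had 0.20 and KCNIP4 within HVC -0.19. Without Scrublet doublets CTSS had -0.19. With 10% of the pooled profile subtracted matrix genes in oligodendrocytes had 0.15 and astrocyte function in microglia 0.38, and lists numbered 2 (of 4) on the glutamatergic side within RA and 1 on the RA side in GABA-1. With a minimum of 50 CPM immediate early genes in microglia had -0.16, and lists numbered 2 on the glutamatergic side within RA, 1 on the RA side in glutamatergic neurons, 16 on the HVC side in non-neuronal classes and 1 on the RA side in GABA-1. With no minimum lists numbered 4 and 5 on the HVC and RA sides in glutamatergic neurons. With random lists matched on the mean of both CPMs GABA-1 had 1 on the RA side. With sums of 0 at 3 UMIs axon guidance had -0.21, MGE genes -0.74, neuropeptides -0.24, upper-layer markers -0.96 and song projection candidates -0.41 in glutamatergic neurons, axon guidance in mural cells 0.19, steroid hormone genes within HVC -0.016, and axon guidance 0.84, OPC markers 1.24 and song projection candidates 1.24 within RA. In RA glutamatergic neurons 16 of 28, 5 of 5 and 9 of 15 members of these lists had 0 UMIs, so the value of OPC markers is set by the 3 UMIs put in their place and shows no change of side (0 against 61 UMIs). The summed UMIs had ratios of 0.853 (0.665 to 1.08) for axon guidance and 0.680 (0.508 to 0.896) for song projection candidates. Between the regions, the glutamatergic list values below 0 likewise rest on the 3 UMIs (107 CPM) put for 0 in RA. Of these lists only MGE genes lay outside the limits. Lists then numbered 3 (of 5) on the glutamatergic side within HVC, 3 (of 10) on the GABAergic side within RA, 1 and 6 on the HVC and RA sides in glutamatergic neurons, and 1 and 0 in GABA-1.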

Other observations

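No hypothesis was tested in this part, and its genes were chosen after their values were seen.

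The Pre clusters, which held HVC cells only, differed in genes of immature and mature neurons. SOX11, a transcription factor of immature neurons, had 1342 CPM in Pre-3 (254 UMIs), 346 in Pre-4 (18 UMIs), 12.9 in Pre-5 (1 UMI, 0.327 to 72.0) and 75.3 in HVC_Glut-1. DCX, which binds microtubules in migrating neurons, had 703 CPM in Pre-3 (589 to 833), 422 in Pre-4 (265 to 640), 116 in Pre-5 (53.2 to 221) and 157 in HVC_Glut-1. The peptide NTS had 37.0 CPM in Pre-3 (14.9 to 76.2), 1191 in Pre-4 (913 to 1526), 1266 in Pre-5 and 1540 in HVC_Glut-1. The sodium channel SCN8A had 89.9 CPM in Pre-3 (52.3 to 144), 595 in Pre-4 (404 to 845), 1524 in Pre-5 and 1622 in HVC_Glut-1, and the potassium channel KCNA1 had 5.29, 269, 853 and 623 CPM. BDNF, a neurotrophin, had 0 UMIs in Pre-3, 2 in Pre-4, 7 in Pre-5 and 28 in HVC_Glut-1. The authors made these clusters on the same cells, so the values describe the clusters and give no order in time.

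Clusters made here separated fibroblast-like cells, 3 from HVC (median 959 UMIs) and 11 from RA (653 UMIs), from the other mural cells, together with 1 cell of another class in each library. The 11 RA and 3 HVC mural cells held 202 and 50 UMIs of COCH, against 13 and 2 in the other mural cells, and 59 and 10 UMIs of ITIH5, against 2 and 2. The collagen gene COL1A1 had 11 UMIs in the RA and 0 in the HVC fibroblast-like cells. The smooth muscle genes MYH11 and ACTA2 had 0 UMIs in them, and in the other mural cells MYH11 was found in 8 of 49 RA cells (23 UMIs, median depth 615) and 1 of 65 HVC cells (1 UMI, 650), and ACTA2 in 9 RA cells and 1 HVC cell. TAGLN, another smooth muscle gene, was close in those other mural cells, with 21 UMIs in 13 RA cells and 18 UMIs in 13 HVC cells.

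Of the 2 libraries, GABA-Pre was also captured mostly in HVC, and its 42 HVC cells had a median of 1463.5 UMIs, a median mitochondrial share of 3.39% and a median ribosomal protein share of 9.83%. Immature neuron markers summed to 17376 CPM in HVC GABA-Pre, 10578 CPM in the 16 HVC GABAergic cells with a high ribosomal share and 2403 CPM in the other 124 HVC GABAergic cells.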
